A study of Rattus norvegicus with 30 samples.

How the data were processed

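Gene expression was measured by RNA sequencing of the left nucleus accumbens of male Sprague-Dawley rats at postnatal day 72. The labels give 30 separately barcoded samples that were not pooled, in 4 groups: enriched and cocaine (8), enriched and saline (7), isolated and cocaine (8), isolated and saline (7). Per the labels, rats arrived at 21 days of age, were housed in either condition for 30 days, received a jugular catheter and then pressed for 0.5 mg/kg of cocaine or for saline at each infusion, 2 h a day for 14 days. A session ended at 30 infusions, and tissue was taken 3 h after the start of the last session.

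The deposited table of read counts, made by the authors, holds 1 whole number per gene and sample and no normalisation. The authors' information sheet names TopHat 2.0.6, Bowtie 2.0.2 and HTSeq 0.5.3p9, while the submitters' processing notes name TopHat2 2.0.4 and FastQC 0.9.1 and the genome build rn4. Neither names the gene annotation or the strand setting. The sheet and the notes also differ in edgeR (3.0.4 against 3.0.8). The authors further deposited, for 14309 genes with over 1 CPM in at least 5 samples per their sheet, group means of normalised signal (counts divided by size factors from DESeq 1.10.1), ratios of those means, and raw and Benjamini-Hochberg adjusted p-values for cocaine, enrichment and their interaction. These deposited means, ratios and p-values are quoted only where named as the authors'. The authors' table of edgeR-normalised counts was not used here.

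The count table lists 22518 genes and 5 entries of the read counter that are not genes (reads in no gene, in more than 1 gene, at more than 1 place, of low quality or unaligned). The 5 entries were left out. On average 55.2% of the counted reads lay in genes, 24.9% in no annotated gene, 19.0% at more than 1 place and 0.901% in overlapping genes. Reads at more than 1 place were not counted, which can lower the counts of genes with near-identical copies and was not tested. Of the genes, 3206 had 0 counts in every sample, and 23 names had been turned into dates and were not matched to any list. Gene counts per sample ran from 14.0 to 45.4 M. No pair of samples within a group (98 pairs) or between groups (337 pairs) held near-identical counts, since the lowest chi-square per degree of freedom was 7.34 where repeated sequencing of 1 library would give about 1.

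The treatment named in the characteristics contradicted the title and source name for 7 of the 15 isolated samples. Group means computed from the counts under either grouping were set against the authors' mean for isolated cocaine rats over 14289 genes. The median difference was 0.00458% when samples were grouped by title and source name and 2.91% when grouped by the characteristic, so the title and source name were used. Lanes came from the sample descriptions. Enriched samples were in lanes 1, 2 and 4, and isolated samples in lanes 5, 6, 7 and 8, except for 1 isolated cocaine sample (22) in lane 4. Among isolated rats, lane 5 held 1 cocaine and 3 saline samples, lane 6 held 3 and 1, lane 7 held 1 and 2 and lane 8 held 2 and 1. Among enriched rats, lanes 1 and 2 each held 2 and 2 and lane 4 held 4 and 3. Drug was thus less evenly spread over lanes in isolated than in enriched rats. In all, 8 samples are named for lane 4, 3 or 4 for each other lane and 0 for lane 3, and the labels also state 4 samples per flow cell without naming flow cells, so whether the 8 ran in 1 lane was not checked.

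Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on the 4 groups (minimum count 10, minimum total 15), which kept 15472 genes, TMM normalisation, and 1 model of the 4 group means fitted by robust quasi-likelihood. Quasi-likelihood F tests, two-sided, were run for 7 contrasts: housing (enriched minus isolated), cocaine (cocaine minus saline), their interaction (the cocaine effect in enriched minus that in isolated rats), housing within each drug and cocaine within each housing. P values were adjusted by Benjamini-Hochberg over the genes of a contrast, and an adjusted p under 0.05 counted as past the threshold. Log2 fold changes are given ± a standard error worked back from the test, as the absolute log2 fold change divided by the square root of F. Levels are TMM-normalised counts scaled to library size (CPM, computed by edgeR) as mean ± SD. The number of samples showing a direction is the number of enriched (or cocaine) samples on the called side of the mean of the isolated (or saline) samples with the same drug (or housing).

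Before the data were examined, 31 gene lists were fixed. Some held immediate early genes, retinoic acid signalling, markers of direct-pathway, indirect-pathway and all striatal projection neurons, of cortical and of septal or other subcortical glutamatergic neurons, of choroid plexus and ependyma, oligodendrocytes, their precursors, astrocytes, microglia, vessels and meninges, red blood cells and striatal interneurons. The others held glucocorticoid-responsive genes, clock genes, glutamate receptors with postsynaptic density genes, GABA genes, neuropeptides, dopamine signalling, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome subunits, heat shock proteins, endoplasmic reticulum stress genes, DNA methylation and histone-modifying enzymes, extracellular matrix, cholesterol synthesis, interferon response with antigen presentation, and BDNF, TrkB and MAPK signalling. Of 686 entries, 659 matched a gene of the table, 15 of them through a synonym in a rat gene reference. Lists with at least 4 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 30 lists tested in each contrast, and again with an estimated correlation and with fry. The score of a list in a sample is the mean of its genes' log2 CPM (prior count 2) centred on each gene.

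The rule for naming genes was also set beforehand. For housing, cocaine and interaction it took up to 10 genes past the threshold in each direction by smallest p, or the 5 with the smallest p where fewer than 5 passed. It also took the 4 members with the smallest p of each list with a camera call or a called member, and 17 genes chosen in advance. For the other contrasts it took up to 5 genes in each direction, or 3 where none passed. The text gives a selection of the genes so taken, and says where a gene was singled out later.

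Alternatives fixed beforehand were median-of-ratios size factors, DESeq2 1.42.0, limma voom with sample weights, no low-count filter, a filter of at least 1 CPM in 7 samples, lane as a factor, 2 surrogate variables (sva 3.50.0), grouping by the treatment characteristic, leaving out the 7 conflicting samples, fitting only the 2 groups compared, and leaving out each of the 30 samples. Added after seeing the data were the ribosomal score, 3 tissue scores (cortical, septal and choroid plexus) and all 4 scores as covariates, and a fit without the 4 samples whose TMM factor was below 0.96. Group labels were also exchanged at random in 100 splits, the real one included. The methods were tested on simulated counts with the depths of these samples. Of 100 genes changed by 0.5 on the log2 scale, edgeR recovered 89 for housing, 71 for cocaine in isolated rats and 55 for the interaction, with 11, 4 and 8 unchanged genes called. A simulated shift of 0.3 in a list of 18 genes was recovered by camera with 0 of 29 other lists called. The simulated genes varied independently of each other and held no lane or tissue differences. The simulation therefore does not show how many genes or lists are called falsely in the real samples.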

Results

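RNA sequencing gave expression profiles of the left nucleus accumbens, the ventral part of the striatum that takes part in reward, from 30 male rats in a 2 by 2 design. Rats were raised in an enriched or an isolated condition and then self-administered cocaine or saline. There were 8 enriched cocaine, 7 enriched saline, 8 isolated cocaine and 7 isolated saline samples. Counts in genes averaged 28.8 ± 3.56 M (SD, n = 8) in enriched cocaine, 27.0 ± 6.21 M (n = 7) in enriched saline, 34.0 ± 5.99 M (n = 8) in isolated cocaine and 37.0 ± 4.97 M (n = 7) in isolated saline samples. The shallowest sample, enriched saline 17, had 14.0 M and the deepest, isolated cocaine 35, had 45.4 M. The 10 most abundant genes held 3.86% of the gene counts on average.

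The first comparison asked which transcripts differed between enriched and isolated rats, averaged over the drug they took. Of 26 measured immediate early genes, which neurons transcribe rapidly after activity, 12 were lower in enriched rats, and the list did not pass with an estimated correlation (adjusted p = 0.256). Nr4a1, an orphan nuclear receptor gene on chromosome 7, fell by 0.83 ± 0.12 on the log2 scale (1.78-fold lower, edgeR adjusted p = 0.000712, 15 of 15 enriched samples lower). It measured 42.3 ± 10.2 CPM (SD, n = 8) in enriched cocaine, 42.6 ± 8.27 (n = 7) in enriched saline, 91.6 ± 21.8 (n = 8) in isolated cocaine and 62.4 ± 17.8 CPM (n = 7) in isolated saline rats. Its relative Nr4a3 on chromosome 5 fell by 1.16 ± 0.18 (2.23-fold) and the zinc finger gene Egr2 on chromosome 20 by 1.07 ± 0.16 (2.10-fold). Fos, a part of the AP-1 transcription factor, fell by 0.67 ± 0.13 (1.59-fold) and Arc, which acts in synaptic plasticity, by 0.65 ± 0.13 (1.57-fold). Each of these 4 genes was lower in 15 of 15 enriched samples, with adjusted p values from 0.000725 (Nr4a3, Egr2) to 0.00494 (Arc).

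Of the 26 immediate early genes, 12 fell, 0 rose and 14 did not pass, and 16 fell when adjusted over the list alone. Their median log2 change was -0.27 (camera adjusted p = 5.02e-08, and adjusted p = 0.256 with an estimated correlation). Egr1 fell by 0.42 ± 0.12 (adjusted p = 0.0245, 13 of 15 samples), a call that was lost when isolated saline sample 27 was left out (adjusted p = 0.050). Npas4 differed by -0.48 ± 0.20 and did not pass (adjusted p = 0.0953, and 0.0442 without enriched cocaine sample 12). The score of the list lay between 0.21 and 0.51 in the 8 isolated cocaine samples and between -0.33 and 0.08 in the 8 enriched cocaine samples. In saline rats the ranges overlapped, from -0.56 to -0.07 in enriched and from -0.29 to 0.35 in isolated samples. Within saline rats 3 of the 26 genes fell (5 adjusted over the list alone, median -0.13, camera adjusted p = 0.0831, adjusted p = 0.871 with an estimated correlation).

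**Figure D1:**
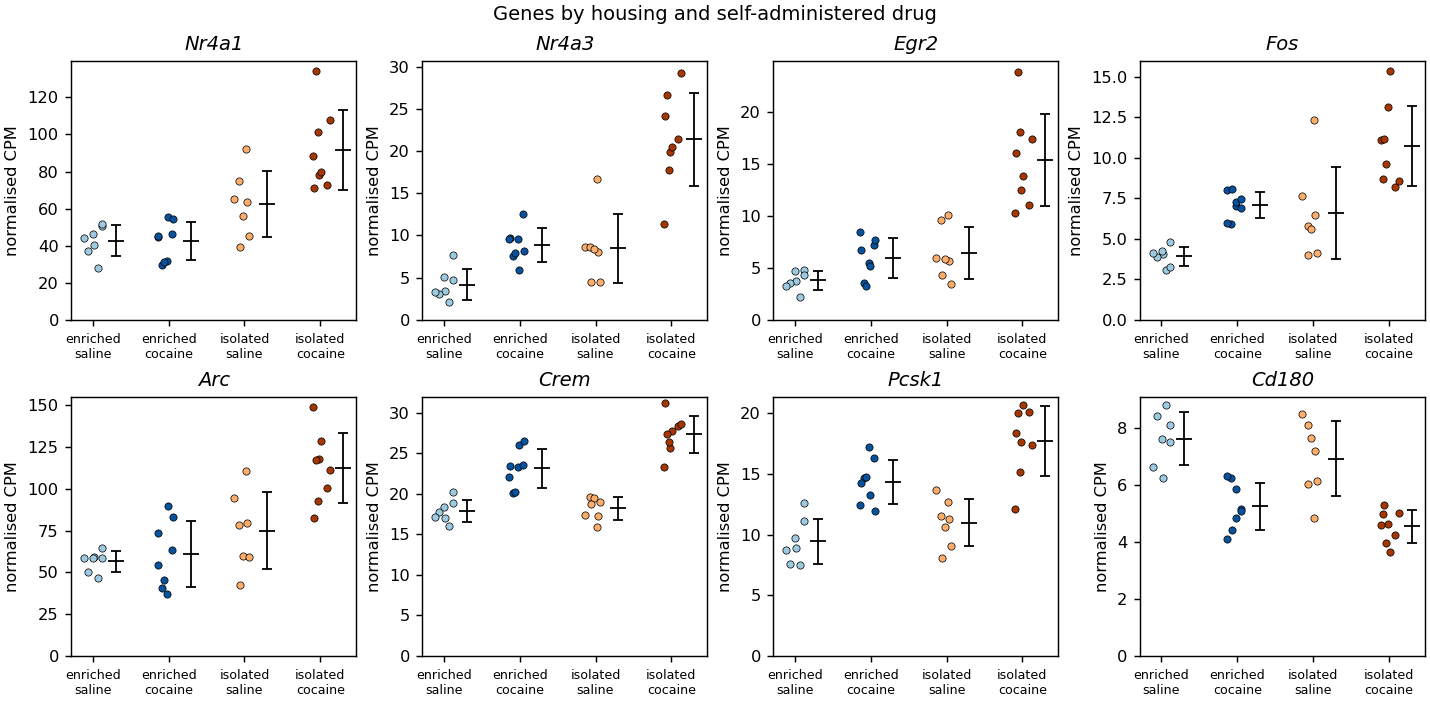
Normalised counts (CPM) of 8 genes, 1 point per sample, in enriched saline (n = 7), enriched cocaine (n = 8), isolated saline (n = 7) and isolated cocaine rats (n = 8), with the mean ± SD beside each group. Nr4a1 averages 91.6 CPM in isolated cocaine rats and 42.3 CPM in enriched cocaine rats, and Crem averages 27.3 CPM and 23.2 CPM after cocaine against 18.2 CPM and 17.9 CPM after saline.

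Some genes of the postsynaptic side and of striatal projection neurons, the main output cells of the accumbens, were also lower in enriched rats. Of 31 measured glutamate receptor and postsynaptic density genes, 6 fell and 0 rose (10 fell and 1 rose adjusted over the list alone, median -0.11, camera adjusted p = 0.000328, adjusted p = 0.256 with an estimated correlation). Among them, Camk2a, a kinase of synaptic plasticity, fell by 0.45 ± 0.09 (1.37-fold, 15 of 15 samples), the scaffold gene Shank2 by 0.25 ± 0.05 (14 of 15) and Dlg2 by 0.46 ± 0.11 (12 of 15). Of 14 projection neuron markers, 6 fell and 0 rose (7 fell adjusted over the list alone, median -0.20, camera adjusted p = 0.000116, adjusted p = 0.483 with an estimated correlation), and their median was 0.037 with the ribosomal and 3 tissue scores as covariates. They include Adcy5, the main adenylyl cyclase of the striatum, at -0.32 ± 0.07 (15 of 15 samples), and Bcl11b, a transcription factor of these neurons, at -0.37 ± 0.09 (14 of 15). The dopamine receptor genes Drd1a (-0.19 ± 0.10, adjusted p = 0.197), Drd2 (-0.12 ± 0.08, adjusted p = 0.281) and Drd3 (-0.34 ± 0.17, adjusted p = 0.173) did not pass. In the dopamine signalling list 1 gene of 19 rose (the vesicular transporter Slc18a2, 0.20 ± 0.06, adjusted p = 0.0216) while 3 fell.

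Chromatin, clock and growth factor genes moved in part the same way. Of 30 DNA methylation and histone-modifying enzymes, 7 fell and 0 rose (12 fell and 3 rose adjusted over the list alone, median -0.05, camera adjusted p = 0.0444, adjusted p = 0.483 with an estimated correlation). The histone deacetylase gene Hdac4 fell by 0.49 ± 0.10, the methylcytosine oxidase gene Tet3 by 0.64 ± 0.14 and the DNA methyltransferase gene Dnmt3a by 0.45 ± 0.11, each in 14 of 15 samples. Of 16 clock genes, 9 fell and 1 rose (10 and 2 adjusted over the list alone, median -0.18, camera adjusted p = 0.00622, adjusted p = 0.292 with an estimated correlation), with Per3 at -0.41 ± 0.10 and Per2 at -0.28 ± 0.07. Of 24 BDNF, TrkB and MAPK signalling genes, 4 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.06, camera adjusted p = 0.0466, adjusted p = 0.256 with an estimated correlation). They include Ntrk2, the BDNF receptor gene, at -0.30 ± 0.08 (11 of 15 samples) and the CREB coactivator gene Mect1, also called Crtc1, at -0.31 ± 0.07 (15 of 15). Bdnf itself was below the count filter.

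Some genes of protein turnover, energy metabolism and ribosomes were higher in enriched rats by small amounts. Of 31 proteasome subunits, 12 rose and 0 fell (19 rose adjusted over the list alone, median 0.11, camera adjusted p = 3.89e-10, adjusted p = 0.483 with an estimated correlation). Psma4 rose by 0.19 ± 0.03 (1.14-fold, adjusted p = 0.00389) and Psmd6 by 0.19 ± 0.04, both in 15 of 15 samples. Of 67 oxidative phosphorylation genes, 9 rose and 0 fell (13 rose adjusted over the list alone, median 0.11, camera adjusted p = 1.26e-10, adjusted p = 0.603 with an estimated correlation), among them the ATP synthase gene Atp5f1 at 0.16 ± 0.04. Of 74 cytosolic ribosomal protein genes, 8 rose and 0 fell, and 0 passed adjusted over the list alone (median 0.14, camera adjusted p = 1.5e-08, adjusted p = 0.603 with an estimated correlation). The ribosomal score of single samples averaged 0.10 in enriched cocaine, 0.10 in enriched saline, -0.03 in isolated cocaine and -0.18 in isolated saline rats, and it ran from -0.17 to 0.64 within enriched saline alone. Among enriched samples the score ran from 0.14 to 0.64 in lane 4 and from -0.29 to 0.02 in lanes 1 and 2. Isolated samples ran from -0.50 to 0.16, so the enriched samples of lanes 1 and 2 lay within their range. Reads at more than 1 place averaged 19.5 ± 0.81% (SD, n = 8) in enriched cocaine and 19.6 ± 0.67% (n = 7) in enriched saline samples. They averaged 18.8 ± 0.52% (n = 8) in isolated cocaine and 18.2 ± 0.46% (n = 7) in isolated saline samples. Whether this bears on the ribosomal genes was not tested. The metallothionein gene Mt2A, which binds metals, rose by 0.43 ± 0.10 (14 of 15 samples), while of 18 glucocorticoid-responsive genes 2 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.653).

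Of 7 septal and other subcortical glutamatergic markers, 2 rose and 0 fell in enriched rats (4 adjusted over the list alone, median 0.33, camera adjusted p = 0.0370, adjusted p = 0.514 with an estimated correlation), and the direction of their test turned with lane as a factor (median 0.055). Zic2, a transcription factor of the septal region, rose by 0.57 ± 0.14 (12 of 15 samples). The septal score averaged 0.33 ± 0.53 (SD, n = 8) in enriched cocaine and -0.34 ± 0.29 (n = 8) in isolated cocaine rats, with -0.00 and 0.01 in the enriched and isolated saline groups. The medians of other cell markers were 0.49 for 13 choroid plexus and ependymal genes, 0.14 for 15 vascular and meningeal genes, 0.11 for 12 interneuron genes, and 0.07 for 12 cortical genes. They were 0.03 for 15 microglia genes, -0.02 for 20 oligodendrocyte genes, -0.04 for 12 astrocyte genes and -0.06 for 9 oligodendrocyte precursor genes. Camera adjusted p values of these 8 lists ran from 0.135 (astrocytes) to 0.882 (vascular), and the test pointed down for the cortical and vascular lists although their medians and means were above 0. Of these lists, 2 oligodendrocyte, 2 astrocyte, 1 cortical and 1 vascular gene fell and the others had 0 called genes. Interferon and antigen presentation genes were higher on balance (22 of 26 positive, median 0.18, camera adjusted p = 0.0256, adjusted p = 0.756 with an estimated correlation), with 0 of 26 called.

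Of the remaining lists, none passed camera for housing. Retinoic acid signalling had 1 of 21 measured genes lower, 0 adjusted over the list alone, a median of 0.02 and a camera adjusted p of 0.572. The lower gene was Rxra, a retinoid receptor gene, at -0.26 ± 0.08 (adjusted p = 0.0383, 13 of 15 samples). Rxra did not pass when any 1 of 13 samples was left out (enriched cocaine 7, 12, 14 and 20, enriched saline 15, 17 and 19, isolated saline 23, 25, 27 and 34, isolated cocaine 33 and 39; adjusted p from 0.0505 to 0.0737). Crabp1, a retinoid-binding protein gene, differed by 0.01 ± 0.11, Rarb was below the filter and Fabp5 was not analysed here. Direct-pathway markers (8 genes, median -0.00, camera adjusted p = 0.703), indirect-pathway markers (4, -0.10, 0.364), GABA genes (18, -0.06, 0.513), neuropeptides (19, 0.05, 0.392), and dopamine signalling (19, -0.07, 0.166) had 0 to 3 called genes in either direction. So did heat shock proteins (18, -0.07, 0.392), endoplasmic reticulum stress genes (19, -0.04, 0.488), extracellular matrix (23, -0.06, 0.267) and cholesterol synthesis (20, 0.03, 0.651, with a mean of -0.01). The neuropeptide genes Pdyn (0.04 ± 0.07), Penk (-0.05 ± 0.09) and Tac1 (0.05 ± 0.09) did not pass. Nor did Cartpt (0.29 ± 0.10, adjusted p = 0.0615, and 0.0490, 0.0437 and 0.0311 without isolated cocaine 22, isolated saline 29 and isolated cocaine 35) or the opioid receptor genes Oprm1 (-0.26 ± 0.21) and Oprk1 (-0.31 ± 0.13). The red blood cell list had too few measured genes to test.

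Over all 15472 genes, 1926 passed for housing, of which 780 were higher and 1146 lower in enriched rats, and 4905 had an unadjusted p under 0.05. The median change of the called genes was 1.18-fold, and 111 changed by more than 1.5-fold. The authors' table has 567 genes past an adjusted p of 0.05 for enrichment, of which 566 were among those called here. The RNA-binding protein genes Elavl3 (-0.26 ± 0.04, adjusted p = 0.000725) and Hnrpd (0.19 ± 0.03, adjusted p = 0.00273) were among the strongest calls, each in 15 of 15 samples. So were the ETS factor gene Etv5 (-0.33 ± 0.05) and the synaptic GTPase-activating gene Sipa1l1 (-0.38 ± 0.06). Housing nearly coincided with sequencing lane, and with lane as a factor the comparison rests on 1 isolated sample in lane 4. In that fit 2 genes passed, 0 of them among the 1926. Of the 78 named housing genes 14 changed sign there, among them Adcy5, Shank3, Rxra, Atp5f1 and Xbp1. The count was 1014 without enriched saline sample 15, 1124 without enriched saline 19, 1209, 1147 and 1098 without isolated saline 23, 25 and 27, 1179 and 1080 without isolated cocaine 33 and 39, and 0 with the ribosomal and 3 tissue scores as covariates.

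**Figure D2:**
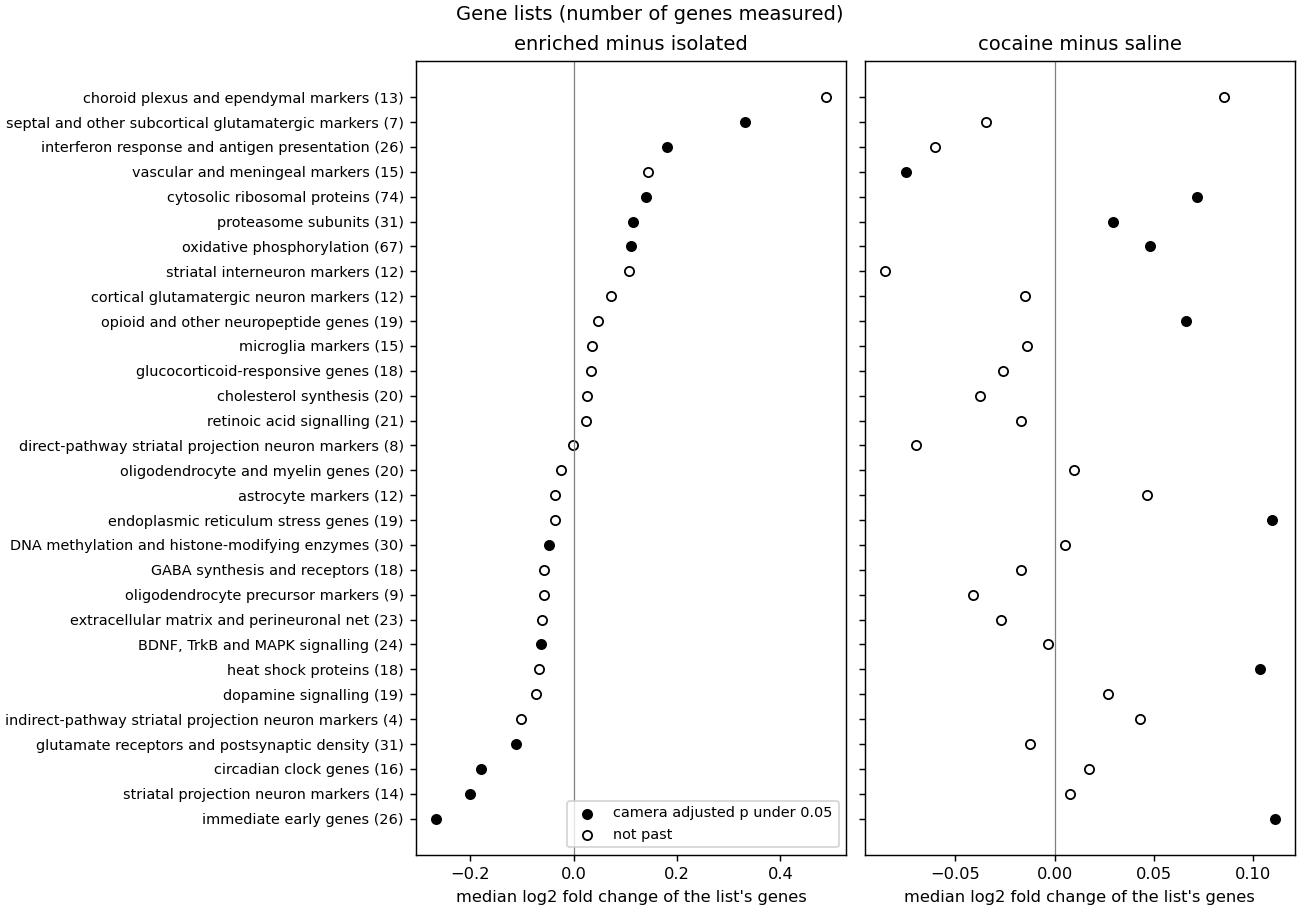
Median log2 fold change of the measured genes of 30 lists for enriched minus isolated (left) and cocaine minus saline (right), with the number of genes in brackets. Filled points have a camera adjusted p under 0.05. Immediate early genes have a median of -0.27 for housing and 0.11 for cocaine.

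Within saline rats, 1125 genes differed between the housing conditions (284 higher and 841 lower in enriched, 4333 at an unadjusted p under 0.05). Btbd14a, a transcriptional regulator gene of the BTB family, fell by 0.84 ± 0.15 and the kinase gene Cit by 0.60 ± 0.11, while the cell cycle regulator Spdya rose by 0.37 ± 0.07 (edgeR adjusted p = 0.0212 for each, 7 of 7 samples). These 3 did not pass without enriched saline 15 or 19 or isolated saline 25 or 27 (adjusted p from 0.0539 to 0.0783). Camk2a (-0.60), Dlg2 (-0.67), Ntrk2 (-0.53), Tet3 (-0.86) and Hdac4 (-0.65) were lower in enriched saline rats (genes singled out after their values were seen). So were 3 of 12 astrocyte markers (3 adjusted over the list alone, 10 of 12 negative, median -0.10, camera adjusted p = 0.0737) and 2 of 9 oligodendrocyte precursor markers (2, 8 of 9, -0.03, 0.139), lists that had an adjusted p of 0.739 with an estimated correlation. The astrocyte score averaged -0.12 ± 0.08 (SD, n = 7) in enriched saline and 0.10 ± 0.13 (n = 7) in isolated saline rats. None of the 8 genes named differed by the interaction test (adjusted p from 0.491 for Btbd14a to 0.629 for Tet3). Proteasome subunits (7 of 31 rose, 17 adjusted over the list alone, median 0.16), oxidative phosphorylation genes (3 of 67 rose, 0 adjusted over the list alone, median 0.17) and ribosomal protein genes (2 of 74 rose, 0 adjusted over the list alone, median 0.22) passed camera. The postsynaptic list did too (5 of 31 fell, 5 adjusted over the list alone, median -0.12), and the 4 lists had an adjusted p from 0.409 to 0.739 with an estimated correlation. The count was 0 without enriched saline sample 15, 0 without enriched saline 19, 0 without isolated saline 27, 2 without isolated saline 25, 129 without isolated saline 23, 651 and 708 without enriched saline 10 and 6, and 1703 without isolated saline 29. It was also 0 with the ribosomal score as a covariate. Enriched saline 15 and 19 were in lane 4, with ribosomal scores of 0.64 and 0.29. Isolated saline 23, 25 and 27 were in lane 5, with scores of -0.30, -0.41 and -0.50. A difference between these lanes therefore cannot be told apart from housing in this count. The median, mean and test differed in sign for the direct-pathway, cortical, septal, vascular, endoplasmic reticulum stress and cholesterol lists, none past camera.

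Within cocaine rats, 30 genes differed by housing (6 higher and 24 lower in enriched, 2057 at an unadjusted p under 0.05). Immediate early genes led here too: Nr4a1 fell by 1.12 ± 0.17 (2.17-fold, edgeR adjusted p = 0.00313), Egr2 by 1.37 ± 0.22 (2.59-fold) and Egr4 by 0.80 ± 0.15 (1.75-fold), each in 8 of 8 enriched samples. Of the 26 genes of the list, 5 fell, 0 rose and 15 fell adjusted over the list alone (median -0.38, camera adjusted p = 3.06e-17, adjusted p = 0.0397 with an estimated correlation). Septal markers passed camera upward (1 of 7 rose, 5 adjusted over the list alone, median 0.71, adjusted p = 0.0988 with an estimated correlation). Projection neuron markers passed it downward (0 of 14 called, 6 fell adjusted over the list alone, median -0.27, adjusted p = 0.138 with an estimated correlation). Zic4, a marker of the septal list, rose by 1.24 ± 0.26 (7 of 8 samples). It lost its call without any 1 of 13 samples (enriched cocaine 1, 3, 7 and 18, enriched saline 17, isolated cocaine 28, 30, 31, 33, 35 and 39, isolated saline 23 and 38; adjusted p from 0.0512 to 0.132). The call of Egr4 was lost without isolated cocaine 39 (adjusted p = 0.0537). By the interaction test the adjusted p was 0.514 for Nr4a1, 0.575 for Egr2 and 0.491 for Egr4 and Zic4. Leaving out single samples moved the count from 5 (without isolated cocaine 39) to 112 (without isolated cocaine 22), and it was 0 with the 3 tissue scores as covariates, 0 without the 7 samples of conflicting labels, 208 by DESeq2 and 116 by limma voom. In all 13 lists passed camera, of which 1 (immediate early genes) passed with an estimated correlation, and the median, mean and test differed in sign for the retinoic acid, oligodendrocyte precursor, astrocyte, glucocorticoid, cholesterol and BDNF lists, none past camera.

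The next comparison asked which transcripts differed between rats that self-administered cocaine and saline, averaged over housing, 3 h after the last session began. Crem, which encodes repressors and activators of cAMP-responsive transcription and lies on chromosome 17, rose by 0.48 ± 0.05 (1.39-fold, edgeR adjusted p = 5.14e-07, 16 of 16 cocaine samples). It measured 23.2 ± 2.38 CPM (SD, n = 8) and 17.9 ± 1.35 CPM (n = 7) in enriched cocaine and saline rats and 27.3 ± 2.33 CPM (n = 8) and 18.2 ± 1.38 CPM (n = 7) in isolated cocaine and saline rats. Nr4a3 rose by 1.22 ± 0.18 (2.34-fold, 16 of 16 samples), Egr4 by 0.77 ± 0.11 (15 of 16), Egr2 by 0.95 ± 0.16 (14 of 16) and Fos by 0.78 ± 0.13 (16 of 16). The cell cycle inhibitor gene Cdkn1a rose by 0.54 ± 0.07, the prohormone convertase gene Pcsk1 by 0.65 ± 0.09, the somatostatin receptor gene Sstr2 by 0.64 ± 0.09 and the MAPK inhibitor gene Spry4 by 0.33 ± 0.05, each in 16 of 16 samples.

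Of 26 immediate early genes, 4 rose, 0 fell and 22 did not pass, with 7 up and 1 down adjusted over the list alone (median 0.11, camera adjusted p = 5.40e-13, adjusted p = 0.0496 with an estimated correlation). Nr4a1 (0.27 ± 0.12, adjusted p = 0.565), Arc (0.35 ± 0.13, adjusted p = 0.391), Egr1 (0.21 ± 0.12, adjusted p = 0.737) and Npas4 (0.48 ± 0.20, adjusted p = 0.501) did not pass. Of 18 heat shock protein genes, 2 rose and 10 rose adjusted over the list alone, 0 fell, and 17 were positive (median 0.10, camera adjusted p = 9.68e-14, adjusted p = 0.0109 with an estimated correlation). These were the cochaperone genes Dnajb5 at 0.27 ± 0.05 and Bag3 at 0.31 ± 0.07. Of 19 endoplasmic reticulum stress genes, 2 rose, 10 rose adjusted over the list alone and 0 fell (median 0.11, camera adjusted p = 1.38e-11, adjusted p = 0.0496 with an estimated correlation). These were Xbp1, a transcription factor of the unfolded protein response, at 0.23 ± 0.04 (16 of 16 samples) and the chaperone gene Hspa5 at 0.24 ± 0.06 (14 of 16). Hspa5 (adjusted p = 0.0463) kept its call only in the fits without enriched cocaine 1 or 12, enriched saline 19, isolated cocaine 22, 31 or 39, or isolated saline 27, 29 or 38. It lost it in the 21 fits without any other single sample (adjusted p from 0.0514 to 0.0903). The clock genes Cry1 (0.29 ± 0.06) and Per2 (0.35 ± 0.07) rose in 16 of 16 samples, with a camera adjusted p of 0.0870 for the 16 clock genes.

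Of the 11 genes lower after cocaine, 4 have roles in immune cells, a group formed after the values were seen. Cd180, a Toll-like receptor homologue of immune cells, fell by 0.57 ± 0.08 (1.49-fold, adjusted p = 0.000213), the microglial receptor gene Gpr34 by 0.37 ± 0.06 and the leukocyte protein gene Lsp1 by 0.49 ± 0.09. The interferon-induced chemokine gene Cxcl11, with 0.127 to 1.48 CPM in the group means, fell by 2.12 ± 0.34, and all 4 were lower in 16 of 16 samples. The acetate-using enzyme gene Acss1 fell by 0.35 ± 0.04 (adjusted p = 4.86e-05) and the transcriptional coactivator gene Cited4 by 0.68 ± 0.14, also in 16 of 16 samples. The 15 microglia markers had 0 called genes and a median of -0.01 (camera adjusted p = 0.636), and the 26 interferon and antigen presentation genes had 0 called and a median of -0.06 (camera adjusted p = 0.237). Of 15 vascular and meningeal markers, 14 were negative with 0 called (median -0.07, camera adjusted p = 0.0317, adjusted p = 0.887 with an estimated correlation). The matrix protease gene Mmp9 rose by 0.72 ± 0.14 (15 of 16 samples) as the 1 called gene of 23 in the extracellular matrix list.

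Small shifts passed camera in 4 other lists for cocaine with 0 genes called: ribosomal proteins (74 genes, median 0.07), oxidative phosphorylation (67, 0.05), proteasome subunits (31, 0.03) and neuropeptides (19, 0.07), with adjusted p values of 0.887, 0.887, 0.887 and 0.444 with an estimated correlation. The other lists did not pass camera for cocaine, and in the cortical, septal, choroid plexus, oligodendrocyte, glucocorticoid, extracellular matrix and BDNF lists the median, the mean and the direction of the test differed in sign. Pdyn (0.17 ± 0.07, adjusted p = 0.548), Penk (0.11 ± 0.09), Tac1 (0.07 ± 0.09), Cartpt (0.03 ± 0.10), Drd1a (-0.13 ± 0.10), Drd2 (0.09 ± 0.08), Drd3 (-0.04 ± 0.17), Oprm1 (0.47 ± 0.21), Oprk1 (-0.01 ± 0.13) and Crabp1 (0.12 ± 0.11) did not pass.

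In all, 53 genes passed for cocaine, 42 higher and 11 lower, and 1210 had an unadjusted p under 0.05. The authors' table has 37 for cocaine, of which 35 were among these 53, and gives Crem ratios of cocaine to saline of 1.29 in enriched and 1.5 in isolated rats. Of the 42 genes that rose with cocaine, 20 were also lower in enriched than in isolated rats, where 3.11 would be expected if the calls were unrelated (Fisher's exact test, two-sided, p = 2.24e-12). They include Nr4a3, Egr2, Egr4, Fos, Pcsk1, Per2, Spry4, Etv5, Dnajb5, Hspa5 and Xbp1, whose housing call was lost without isolated cocaine 30 (adjusted p = 0.0503). Both contrasts use the same samples, so a gene high in isolated cocaine rats alone can be called in both. The p value of the overlap therefore overstates the evidence. With lane as a factor 28 genes passed, with samples grouped by the treatment characteristic 0, without the 7 samples of conflicting labels 23, by DESeq2 105 and by limma voom 143.

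Within isolated rats, 18 genes passed for cocaine (14 higher, 4 lower, 1653 at an unadjusted p under 0.05). Crem rose by 0.59 ± 0.07 (1.5-fold, edgeR adjusted p = 1.15e-05), Egr4 by 1.06 ± 0.15 (2.09-fold) and the MAPK phosphatase gene Dusp5 by 0.72 ± 0.12, each in 8 of 8 samples. Fam46b, of a nucleotidyltransferase family, at 0.963 CPM after cocaine and 0.185 CPM after saline, rose by 2.36 ± 0.32 (5.15-fold, 8 of 8 samples). Acss1 fell by 0.42 ± 0.06, Cd180 by 0.61 ± 0.11, Fam184b by 0.63 ± 0.13 and Cxcl11 by 2.49 ± 0.52. Of the 26 immediate early genes, 3 rose and 12 rose adjusted over the list alone (median 0.23, camera adjusted p = 6.75e-14, adjusted p = 0.0654 with an estimated correlation). The count was 28 without isolated saline 29, 1 without the 7 samples of conflicting labels, 4 with lane as a factor and 0 when grouped by the treatment characteristic. Calls were lost for Cd180 without isolated saline 34 (adjusted p = 0.0552) and for Fam184b without isolated saline 23, 25, 27 or 32 or isolated cocaine 28, 31, 33, 35 or 39 (0.0514 to 0.101). The call of Cxcl11 was lost without isolated cocaine 22, 24, 28, 30, 31, 33, 35 or 39 or isolated saline 34 or 38 (0.0535 to 0.192). In all 8 lists passed camera, all upward, and 0 passed with an estimated correlation. The median, mean and test differed in sign for the retinoic acid, oligodendrocyte, glucocorticoid, DNA methylation and extracellular matrix lists, none past camera.

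Within enriched rats, the smallest adjusted p for cocaine was 0.0834, and edgeR called 0 genes, with 832 at an unadjusted p under 0.05, 26 genes past by DESeq2 and 21 by limma voom. With lane as a factor 5 genes passed, among them Crem (adjusted p = 0.0218), Spry4, Fos and Acss1 (adjusted p = 0.0319 for each). In the fit without lane Crem differed by 0.37 ± 0.07, Spry4 by 0.36 ± 0.07 (adjusted p = 0.0906), Pcsk1 by 0.61 ± 0.12, Lsp1 by -0.59 ± 0.12 and Gpr34 by -0.38 ± 0.08, each in 8 of 8 samples. Heat shock proteins (18 of 18 positive, median 0.12, adjusted p = 0.315 with an estimated correlation), endoplasmic reticulum stress genes (16 of 19, 0.11, 0.315), septal markers (7 of 7, 0.32, 0.315) and astrocyte markers (12 of 12, 0.07, 0.319) passed camera. The effects in the housing conditions did not differ by the interaction test for Crem (-0.22 ± 0.09, adjusted p = 0.522), Egr4 (-0.59 ± 0.21, adjusted p = 0.491) or Dusp5 (-0.49 ± 0.17, adjusted p = 0.491). Nor did they for Fam46b (adjusted p = 0.511), Acss1 (0.617), Cxcl11 (0.728), Fam184b (0.751) or Cd180 (0.891). The count was 3 without enriched cocaine 1, 2 without enriched saline 15, enriched saline 17 or isolated saline 27, and 1 without enriched cocaine 18, isolated cocaine 24 or isolated cocaine 33. Crem passed in each of these 7 fits (adjusted p from 0.0201 to 0.0466), Pcsk1 without enriched saline 15 (0.0373) and Gpr34 without enriched cocaine 1 (0.0329). The median, mean and test differed in sign for the cortical, glucocorticoid, dopamine and proteasome lists, none past camera.

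The last comparison asked whether the difference after cocaine depended on housing. For the interaction, edgeR called 0 genes, DESeq2 0 and limma voom 0, with 1408 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.491. The authors' table also has 0 genes for this term. The smallest p values belonged to Smoc1, a matrix protein gene (0.88 ± 0.19), and Htr1a, a serotonin receptor gene at 0.599 to 1.53 CPM in the group means (2.02 ± 0.50). Next came the phosphatase gene Dusp2 (-0.52 ± 0.14) and the RNA-binding protein gene Ewsr1 (-0.20 ± 0.05), none past the threshold. Immediate early genes had a smaller cocaine difference in enriched than in isolated rats on balance (22 of 26 negative, median -0.21, camera adjusted p = 6.31e-05, adjusted p = 0.744 with an estimated correlation), with Egr4 at -0.59, Junb at -0.43 and Nr4a1 at -0.57. Septal markers went the other way (7 of 7 positive, median 0.46, camera adjusted p = 0.00121, adjusted p = 0.744 with an estimated correlation), as did Zic4 (1.48 ± 0.37), while Penk (-0.50 ± 0.17) and Drd2 (-0.33 ± 0.16) were negative without passing. Camera also passed, with 0 genes called, for indirect-pathway (4 genes, median -0.33) and all projection neuron markers (14, -0.20), astrocyte (12, 0.09) and interneuron markers (12, 0.32). It passed likewise for GABA genes (18, 0.10), oxidative phosphorylation (67, -0.12), ribosomal proteins (74, -0.16) and proteasome subunits (31, -0.07), with adjusted p values from 0.744 to 0.785 with an estimated correlation. The median, mean and test differed in sign for the vascular, glucocorticoid, clock, extracellular matrix and cholesterol lists, which did not pass.

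Across genes, which are not independent replicates, the cocaine effects in enriched and in isolated rats had a Pearson correlation of -0.04 and a Spearman correlation of -0.15. The housing effects in saline and in cocaine rats had a Pearson correlation of 0.38 and a Spearman correlation of 0.43. Among 100 splits with exchanged labels, 90 and 64 gave correlations of the cocaine effects as large, and 14 and 9 gave correlations of the housing effects as large. Without the 4 samples of low TMM factor (enriched cocaine 14 and 20, enriched saline 15, isolated cocaine 35), 74 genes passed for the interaction, 70 positive and 4 negative, and without isolated saline 29 1 gene passed.

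**Figure D3:**
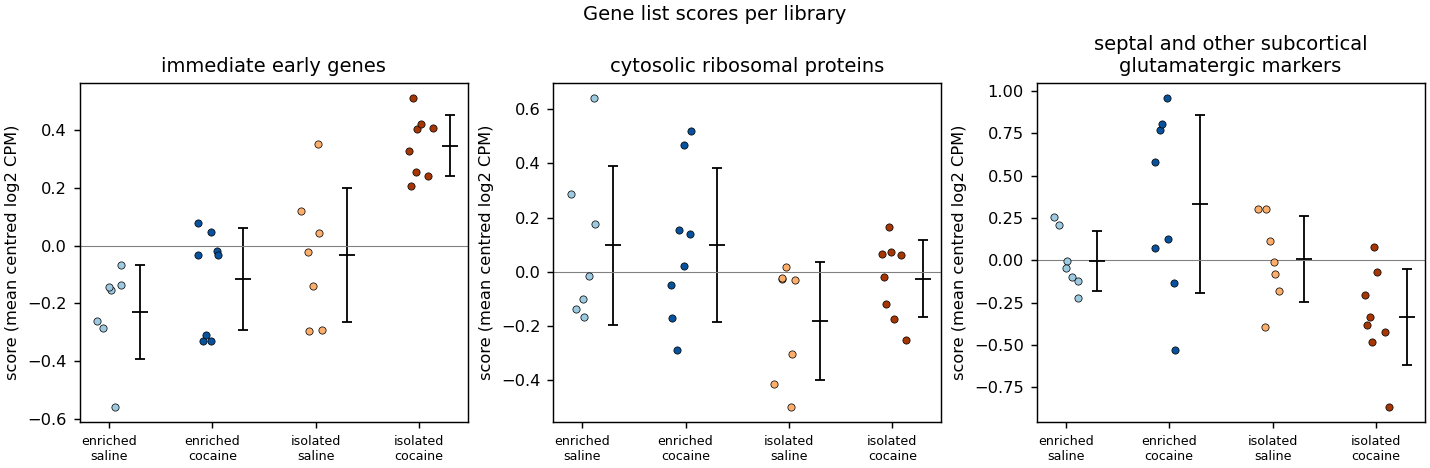
Scores of 3 gene lists in each sample by group, as the mean log2 CPM of the list's genes centred on each gene, with the mean ± SD beside each group. The immediate early gene score of the 8 isolated cocaine samples runs from 0.205 to 0.51, and the septal score averages 0.33 in enriched cocaine and -0.34 in isolated cocaine rats.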

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

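The tests of the ribosomal score for the housing genes and of the vascular score for the immune genes were set out before their results were seen, and the other tests of explanations given here were chosen only after the results were seen. In 372 groups of 7 or 8 values (a measure or a named gene in the samples of 1 group), 19 samples lay far from the others of their group by Dixon's test. Chance alone gives such a sample in about 1 in 20 groups, so the number of far samples is about what chance gives. Enriched saline sample 17 had 14.0 M gene counts against 27.0 to 34.3 M in the others of its group, and isolated cocaine sample 31 had a choroid plexus score of -0.72 against -0.30 to 0.03.

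Among genes, isolated saline sample 27 was high for Nr4a3 (16.7 CPM, others 4.45 to 8.68), Per3 (45.03, others 29.8 to 33.9) and Dnmt3a (28.6, others 16.4 to 21.4). Isolated cocaine sample 39 was high for Elavl3 (97.3 CPM, others 72.2 to 81.8) and Shank3 (856 CPM, others 476 to 653). Enriched saline sample 15 was high for Rps14 (56.4 CPM, others 3.86 to 13.1) and Spdya (10.2, others 8.72 to 9.36) and low for Mect1 (14.8, others 20.8 to 24.3). Isolated cocaine sample 30 was high for Drd3 (3.43 CPM, others 1.098 to 1.88) and Oprk1 (7.18, others 3.23 to 4.56). Zic2 was high in enriched saline sample 10 (48.4 CPM, others 14.6 to 25.9) and isolated saline sample 25 (22.8, others 13.3 to 17.3). Single samples were far for Mt1a (enriched saline 19, 29.2 CPM, others 15.0 to 20.6), Drd2 (enriched saline 6, 280 CPM, others 305 to 320), Tac1 (isolated saline 34, 249 CPM, others 384 to 477), Oprm1 (enriched cocaine 7, 2.04 CPM, others 0.629 to 1.29) and Smoc1 (enriched cocaine 1, 7.33 CPM, others 3.86 to 5.4).

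The cocaine difference of 10 gene lists differed between enriched and isolated rats by camera with the preset correlation, and none did with an estimated correlation (adjusted p from 0.744 to 0.785). The median of the interaction was -0.21 for immediate early genes, -0.33 for indirect-pathway markers, -0.20 for projection neuron markers, 0.46 for septal markers, 0.085 for astrocyte markers, 0.32 for interneuron markers, 0.10 for GABA genes, -0.12 for oxidative phosphorylation, -0.16 for ribosomal proteins and -0.072 for proteasome subunits.

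The first pattern weighed is the 1926 genes that differed between enriched and isolated rats. Of 100 splits with exchanged housing labels, 1 (the real one) gave as many, and the highest other gave 1, so a random grouping of single samples would rarely give as many. With the cortical, septal and choroid plexus scores as covariates 704 of the 1926 genes still passed, so these 3 scores did not account for all of the calls. The other genes lost their calls, and scores of a few markers may remove only a part of a tissue difference. Other tissue as a cause therefore stays open. Within groups, 92.0% of the genes followed the ribosomal score in the direction of their housing difference, against 70.8% of the genes that did not pass, and the slope within groups gives a median of 32.5% of a gene's difference, so RNA composition may account for a part. With the ribosomal score as a covariate 108 genes passed (100 of the 1926) and with all 4 scores 0, so how large that part is stays open. Among enriched samples the score was higher in lane 4 than in lanes 1 and 2, so the ribosomal score and lane cannot be fully told apart. The share of reads at more than 1 place was also higher on average in enriched samples, and its part in the score was not tested. Sequencing lane, with 2 genes past the threshold when it was a factor, cannot be told apart from housing because 1 isolated sample shares a lane with enriched samples, and an effect of housing on the tissue itself stays open.

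The second pattern is the lower level of 12 immediate early genes in enriched rats. Of 100 splits, 1 (the real one) gave as many lower genes, and the highest other gave 0, but the other splits called at most 1 gene for housing in all. The median difference of the 26 genes was -0.27 (1 of 100 splits as large, the next -0.26), and it was -0.23 with the ribosomal score as a covariate (6 genes lower) and -0.22 with the 3 tissue scores (8 genes lower), which argues against either as the whole cause. With all 4 scores the median was -0.13 with a median standard error of 0.10 and 0 genes passed, while the list still passed camera with the preset correlation (adjusted p = 1.64e-10, unadjusted p = 0.0051 with an estimated correlation), so both together could account for a part. In the main fit the unadjusted camera p with an estimated correlation was 0.0256, which did not pass after adjustment over the lists. With lane as a factor the median was -0.33 with a median standard error of 0.28 and 0 genes passed, and the list passed camera (adjusted p = 1.47e-05, unadjusted p = 0.0579 with an estimated correlation), so lane and housing, a biological difference that the design names, cannot be told apart.

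The third pattern is the lower level of Cd180, Gpr34, Lsp1 and Cxcl11 after cocaine. A loss of microglia would lower their markers by about as much, and the median of 15 microglia markers was -0.0140 (SD 0.108, from -0.17 to 0.18), which argues against fewer microglia. With the vascular and meningeal score as a covariate the 4 genes kept 89.4% of their median difference and all 4 still passed, which argues against less meningeal tissue as the whole cause. A change of these transcripts within cells after cocaine stays open as a hypothesis and was not tested.

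For the other counts of genes, 1 of 100 splits with exchanged drug labels gave as many as the 53 genes for cocaine (highest other 2) and 1 as many as the 18 for cocaine in isolated rats (highest other 2). Of 100 splits with exchanged housing labels, 1 gave as many as the 1125 genes for housing in saline rats (highest other 640) and 2 as many as the 30 for housing in cocaine rats (highest other 313). A random grouping of single samples thus rarely gave as many for cocaine, for cocaine in isolated rats or for housing in saline rats. For the 30 genes of housing in cocaine rats chance is not excluded. Another split gave 313 genes there, and leaving out single samples moved the count from 5 to 112. Leaving out single samples moved the count for housing in saline rats from 0 to 1703. With drug labels exchanged, 1 split called 4058 housing genes under the saline label and 0 under the cocaine label. Another called 0 and 4639. The counts of 1125 and 30 therefore do not show that housing mattered more in saline rats. The splits exchanged samples across lanes, so they decide nothing about lane. For the 0 genes of the interaction 100 of 100 splits gave as many (highest other 3631) and for the 0 genes of cocaine in enriched rats 100 of 100 (highest other 68), but every split gives at least 0, so the splits decide nothing there. Splits that call 3631 or 313 genes point to a structure of the samples. In the split with 3631 the housing effects in saline and in cocaine rats had a Pearson correlation of -0.63, so the housing difference itself could be that structure, and the cause was not tested.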

How the results depend on the processing

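The alternatives were fixed before the data were examined except 4 (the ribosomal score, the 3 tissue scores, all 4 scores as covariates, and the fit without 4 samples of low TMM factor) and the recomputed correlations, which were chosen only after the results were seen. Over the alternatives other than those leaving out a single sample, 3116 gene values kept direction and side of the threshold. The rest became weaker (559), stronger (73) or reversed (23). Genes that passed in neither the main fit nor the alternative add to the 3116. Of the 78 named genes called for housing, 78 still passed by DESeq2 and 71 when grouped by the treatment characteristic. Fewer still passed by limma voom (47), with surrogate variables (37) or without the 7 conflicting samples (36). With lane as a factor 0 of the 78 still passed and 14 changed sign, and housing cannot be told apart from lane in that fit. With the ribosomal score 24 still passed, and with all 4 scores 0. Of the list values 809 kept direction and side of the threshold, 128 became weaker, 35 stronger and 24 reversed. Lists were recomputed for housing, cocaine and interaction, and in the other contrasts for the immediate early, heat shock and endoplasmic reticulum stress lists. No list was tested with its own score as a covariate. Except where named, the cause was not tested.

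With lane as a factor, the counts of genes were 2 for housing, 28 for cocaine, 0 for housing in saline, 2 for housing in cocaine, 5 for cocaine in enriched and 4 for cocaine in isolated rats. With 2 surrogate variables they were 603, 176, 0, 251, 16 and 41 in the same order. DESeq2 gave 105 for cocaine, 1916 for housing in saline, 208 for housing in cocaine, 26 for cocaine in enriched and 73 for cocaine in isolated rats. Limma voom gave 638 for housing, 143 for cocaine, 116 for housing in cocaine, 21 for cocaine in enriched and 145 for cocaine in isolated rats. Grouped by the treatment characteristic, which contradicts the title and source name for 7 isolated samples, the counts were 0 for cocaine, 1756 for housing in saline, 0 for housing in cocaine and 0 for cocaine in isolated rats. Without the 7 conflicting samples, with fewer samples, they were 282 for housing, 23 for cocaine, 0 for housing in cocaine, 2 for cocaine in enriched and 1 for cocaine in isolated rats. Fitting the 2 groups alone gave 1871 for housing in saline, 5 for housing in cocaine and 1 for cocaine in enriched rats.

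With the ribosomal score as a covariate, 108 genes passed for housing, 0 for housing in saline and 1 for cocaine in enriched rats. With the 3 tissue scores, 846 passed for housing, 126 for cocaine, 0 for housing in cocaine and 3 for cocaine in enriched rats. With all 4 scores, 0 passed for housing, 186 for cocaine, 0 for housing in saline, 0 for housing in cocaine and 6 for cocaine in enriched rats. Without the 4 samples of low TMM factor, 912 passed for housing, 74 for the interaction, 217 for housing in cocaine, 3 for cocaine in enriched and 33 for cocaine in isolated rats.

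Leaving out 1 sample gave 1014 to 2693 genes for housing, 46 to 69 for cocaine, 0 to 1 for the interaction, 0 to 1703 for housing in saline, 5 to 112 for housing in cocaine, 0 to 3 for cocaine in enriched and 14 to 28 for cocaine in isolated rats. For housing in cocaine rats the count was 7, 8, 49, 46, 62, 8 and 101 without enriched cocaine 1, 7, 12, 14, 16, 18 and 20. It was 19, 19, 15 and 17 without enriched saline 10, 13, 17 and 19. It was 112, 47, 15, 14, 8, 11, 10 and 5 without isolated cocaine 22, 24, 28, 30, 31, 33, 35 and 39, and it was 15, 17 and 15 without isolated saline 23, 29 and 38. The correlations of the cocaine effects ran from -0.16 to 0.09 (Pearson) and -0.30 to 0.01 (Spearman), and those of the housing effects from 0.21 to 0.48 and 0.26 to 0.54.

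The Pearson correlation of the cocaine effects was 0.24 with surrogate variables, 0.26 with tissue scores and 0.23 with all 4 scores, and the Spearman correlation 0.10, 0.16 and 0.13. The Pearson correlation of the housing effects was 0.61 with tissue scores, 0.78 with lane, 0.062 by limma voom and 0.14 with no filter, and the Spearman correlation 0.70 with lane and 0.083 by limma voom. With lane as a factor the housing effects in saline and in cocaine rats rest on the same isolated cocaine sample in lane 4. They share its error, which can raise their correlation, so the values with lane do not show that the effects are alike.

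With lane as a factor the housing difference reversed for Trappc6b (-0.0019), Rxra (0.038), Adcy5 (0.048), Gng7 (0.069), Foxp1 (0.15), RGD1306622 (0.052), Mobp (0.27) and Shank3 (0.11). It also did so for Atp5f1 (-0.0084), Uqcrfs1 (-0.012), Psmd14 (-0.023), Xbp1 (0.0094), Fdps (-0.043) and Plcg1 (0.11). For these genes a reversal is a change of sign only. The values rest on 1 isolated sample in lane 4 and some are very small, so they do not show an opposite difference. For lists, a reversal is one of the direction of the camera test, and the value given is the median. The median kept its sign for septal and vascular markers in housing, for interneuron markers in the interaction without the 7 conflicting samples and for ribosomal proteins with surrogate variables. With lane as a factor the test reversed for septal markers (0.055), oligodendrocyte genes (0.30) and interneuron markers (-0.14). With all 4 scores Trpc4 (-0.093), Rpl37 (-0.18), projection neuron markers (0.037) and vascular markers (0.20) reversed for housing and projection neuron markers (0.061) for the interaction, as they did with the tissue scores (0.064). With surrogate variables the median was 0.0047 for ribosomal proteins in housing, and 0.014 for oxidative phosphorylation and 0.0067 for proteasome subunits in the interaction. Grouped by the characteristic, Cacng6 (0.053) reversed for cocaine, and Fam46b (-0.90), Egr4 (-0.28), Cdkn1a (-0.036), Dusp5 (-0.16), Acss1 (0.028), Cxcl11 (1.53) and the immediate early list (-0.015) for cocaine in isolated rats. In that grouping, lists reversed for cocaine (immediate early -0.0024, indirect-pathway -0.13, projection neuron -0.15, interneuron 0.20, dopamine -0.094) and for the interaction (immediate early 0.13, indirect-pathway 0.042, projection neuron 0.21, interneuron -0.22, clock 0.14). Without the 7 conflicting samples, projection neuron markers reversed for cocaine (-0.063) and the interaction (0.039), and interneuron markers for the interaction (0.022).

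In simulated counts at the depths of these samples, edgeR recovered 55.0% of genes changed by 0.5 on the log2 scale for the interaction, 71.0% for cocaine in isolated rats and 89.0% for housing. Neither depth nor sample number was varied there, so what depth alone limits was not tested.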

Other observations

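The overlap of calls, the splits and the comparisons of lanes were tests chosen only after the results were seen. Of the 42 genes higher after cocaine, 20 were among the 1146 lower in enriched rats, where 3.11 would be expected if the calls were unrelated, and of the 11 lower after cocaine 2 (Cxcl11 and Lsp1) were among the 780 higher in enriched rats, where 0.555 would be expected (Fisher's exact test, two-sided, p = 2.24e-12 and p = 0.103). The genes are not independent of each other, and both contrasts use the same samples, so these p values overstate the evidence. A gene that stands out in isolated cocaine rats alone can be called in both.

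Across genes, the cocaine effects in enriched and in isolated rats had a Pearson correlation of -0.04, and 90 of 100 splits with exchanged drug labels gave one as large (highest other 0.48). Their Spearman correlation was -0.15, and 64 of 100 splits gave one as large (highest other 0.60). The housing effects in saline and in cocaine rats had a Pearson correlation of 0.38, with 14 of 100 splits as large (largest other -0.63), and a Spearman correlation of 0.43, with 9 of 100 splits as large (largest other -0.70). Chance cannot be excluded for any of these 4 correlations.

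Between lanes within a housing condition, 22 genes differed among the 15 enriched samples (3 lanes, 1668 genes at an unadjusted p under 0.05) and 2 among 14 isolated samples (4 lanes, 1626 genes), by edgeR with drug in the model. These fits hold fewer samples than the housing contrast and spread them over more groups. Their counts therefore cannot be set against the number of housing genes and do not show that lanes differ little. The cortical score had an SD of 1.02 in enriched cocaine, 1.09 in enriched saline, 0.72 in isolated cocaine and 0.99 in isolated saline samples, and it ran from -1.62 to 1.45 over all samples.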
